A study of Homo sapiens with 18 samples.

How the data were processed

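RNA sequencing measured gene expression in 18 libraries from 3 human cancer cell lines named in the labels: MHCC-97H (liver), MDA-MB-231 (breast) and HCT-116 (colon). Cells received DMSO, the solvent control, or 20 nM H3B-8800, a small molecule that modulates the splicing factor SF3B1, for 24 h in medium with 10% serum. Each of the 6 groups held 3 libraries. The labels do not state whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between samples. Groups were taken from the labels alone, and each group is named by the line on its label.

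The deposited table holds counts, made by the authors: whole-number read counts for 20263 Ensembl genes, with no normalization. The submitters' processing notes name fastp, HISAT2 and the build GRCh38. Their versions, the counting tool, the annotation release, the strand setting and the library kit are not given in the sources used here. Library totals ran from 28232315 to 41488278 counts. A count of 0 over the 6 libraries labelled MHCC-97H allows up to 0.0142 CPM (counts scaled to a common library total), the level of 3 counts, which covers counting error only. Gene names, coordinates, exonic length, intron number and transcript GC content came from GENCODE release 29 on GRCh38, which held 20224 of the 20263 genes. Genes whose exons overlap another gene are named as such, because the strand setting is not given.

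The following choices were made before the data were examined. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with 1 mean per group over all 18 libraries, using TMM scaling, filterByExpr by group, estimateDisp, and the robust quasi-likelihood F test. This left 14234 genes. A gene is called at a Benjamini-Hochberg adjusted p under 0.05, and calls with a log2 fold change of at least 1 in size were counted separately. Adjusted p-values for single genes are from edgeR unless another tool is named. The H3B-8800 effect was tested under each line label. Its difference between labels was tested by an interaction over the 3 labels and by the 3 pairwise differences. Values in CPM are scaled by TMM and given as mean ± SD with n = 3, except marker genes of cell types, which are CPM of the library total. Folds on the log2 scale carry the standard error of the fit.

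Also fixed in advance were 43 gene lists. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 129 tests (43 lists under 3 labels), and again with an estimated correlation. Camera compares the members of a list with the other genes. The fry test, run beside it, asks only whether the members of a list move on balance one way. Genes were named by a rule. It took SLK, ENO1 and SF3B1. It took up to 8 called genes with the largest rise and 8 with the largest fall, among genes averaging at least 10 CPM whose treated libraries all lay on one side of the controls. It took up to 4 members of each list in order of adjusted p. Across labels it took the 8 genes with the smallest adjusted p of the interaction, those moving one way under all labels, and those with the largest pairwise differences. Fold changes of pairs of labels were correlated across genes. Single-exon coding genes were compared with other coding genes by camera.

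Alternatives set in advance were relative log expression, upper-quartile and library-total scaling, no filter, a filter of 50 counts in 3 libraries, and removal of the 10 most abundant genes. Further ones were a block for the replicate number, glmTreat against a log2 fold change of 1, limma voom, DESeq2 1.42.0, separate fits of the 6 libraries of a label, and leaving out each library. Alternatives chosen after seeing the data removed a per-library trend on GC content and exonic length (natural splines with 5 degrees of freedom), alone or with the block, and thinned the 6 libraries labelled MHCC-97H to 1 total. Comparisons between line labels, and a fit of 12 libraries carrying the other 2 labels, were also chosen after seeing the data, as was an exact test of the mitochondrially encoded share of counts with the HCT-116 libraries paired.

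The replicate numbers were checked for pairing by correlating, across genes, deviations from the group means of same-numbered treated and control libraries. Under the HCT-116 label all 3 correlations exceeded 0.1 (0.13, 0.33 and 0.14), so these numbers were treated as possible pairs. The main fits and list tests were nevertheless unpaired. Pairing entered only through the replicate block, which covered the numbers of all 3 labels, and the paired test of the mitochondrially encoded share. The labels do not say what a number marks. Control 1 of this label correlated more with a treated library of another number (0.24), so the pairing is uncertain. For controls 2 and 3 the highest such value was -0.09 and -0.03. Same-numbered libraries correlated at -0.02, 0.14 and 0.03 under the MHCC-97H label and at 0.22, 0.08 and 0.06 under the MDA-MB-231 label. Those numbers were not treated as pairs outside the block.

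The fit was tested on simulated data with 200 changed genes per label. It recovered 76.1% of changes of size 1 on the log2 scale under the MHCC-97H label, 80.6% under MDA-MB-231 and 86.6% under HCT-116, and at most 5.04% of calls were false. A simulated trend on GC content alone gave 3409 calls, of which 3248 were false. With the trend on GC content and exonic length removed the fit gave 143 calls, of which 9 were false. No trend on length was simulated, so its removal was not checked. Some genes that the naming rule or the lists took are not reported here by name. Exon skipping is not measured by gene counts and was not analysed here.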

Results

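The series title concerns skipping of an SLK exon, the enzyme ENO1 and glycolysis, and the design contrasts H3B-8800 with DMSO in each line. Gene-level RNA sequencing counts were compared between 3 treated and 3 control libraries under each of 3 line labels. Totals per library ran from 28232315 to 41488278 counts. Positions are on GRCh38.

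The libraries labelled MDA-MB-231 and those labelled HCT-116 shared one expression profile. KRT20, LGALS4, VIL1 and CDH17, genes of intestinal epithelium, averaged 898, 417, 204 and 101 CPM under the MDA-MB-231 label and 912, 416, 214 and 105 CPM under the HCT-116 label (n = 6 each). All 4 had 0 counts in the 6 libraries labelled MHCC-97H, which allows up to 0.0142 CPM. VIM, the mesenchymal filament vimentin, averaged 19.6 and 22.1 CPM under the MDA-MB-231 and HCT-116 labels against 1190 CPM under the MHCC-97H label. Other epithelial and mesenchymal genes were split. The epithelial genes CDH1 (22.1 and 26.1 against 0.00948 CPM) and KRT19 (810 and 827 against 0.0731 CPM) went with VIM. So did the mesenchymal gene TWIST1 (0 and 0 against 11.7 CPM). EPCAM, FN1 and CDH2 were among those that went the other way. The epithelial gene EPCAM averaged 0.0176 and 0.0808 CPM against 16.3 CPM. The mesenchymal genes FN1 (8720 and 9120 against 130 CPM) and CDH2 (129 and 128 against 23.2 CPM) were lower under the MHCC-97H label. The liver gene ALB was at 17.2 CPM under the MDA-MB-231 label, 21.2 CPM under the HCT-116 label and 0 counts under the MHCC-97H label. KRT17 averaged 1510 CPM under the MHCC-97H label and 0.241 and 0.188 CPM under the others. These genes were picked from the fixed marker lists after their values were seen.

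**Figure D1:**
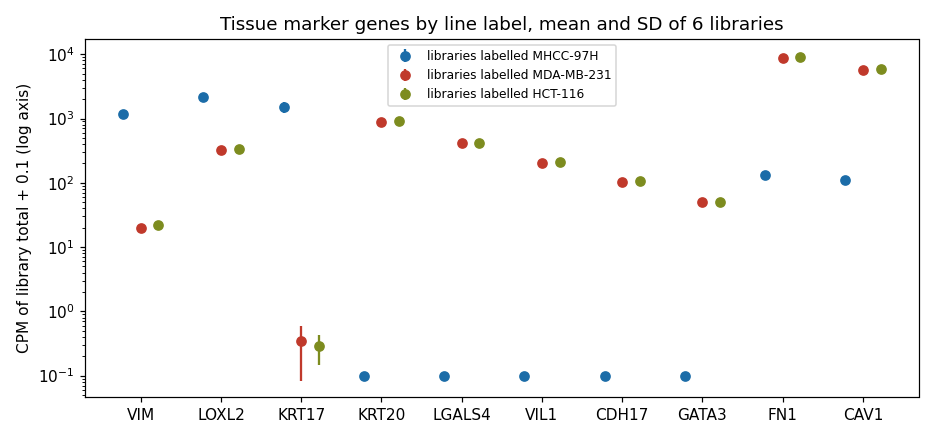
Marker genes of tissues (x axis) against CPM of the library total plus 0.1 (y axis, log scale), as mean and SD of the 6 libraries of each line label. Points of the MDA-MB-231 and HCT-116 labels nearly coincide (KRT20 898 and 912 CPM), while those of the MHCC-97H label lie apart (KRT20 0 CPM).

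Between the DMSO libraries labelled MDA-MB-231 and HCT-116, edgeR called 5 of 14234 genes, namely MYADM, RNF138, PSAT1, PNKD and SEC24C, with 588 at an unadjusted p under 0.05. Between the DMSO libraries labelled MHCC-97H and MDA-MB-231 it called 11772 genes (82.7%). Across 10625 genes, log2 CPM of libraries with the labels MDA-MB-231 and HCT-116 correlated at a median r of 0.986 (36 pairs of libraries, 0.976 to 0.989). Either label against MHCC-97H gave 0.374 to 0.423. Genes are not independent replicates, so these r carry no p. Over the 12 libraries together, edgeR called 0 genes by line label, with 524 at an unadjusted p under 0.05. Which line each library holds was not tested, since no reference profile of a line was compared. It stays open for every label, so results for the labels MDA-MB-231 and HCT-116 are not evidence from separate lines.

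In the libraries labelled MHCC-97H, SLK, a kinase of the STE20 group, rose after H3B-8800, and ENO1, which makes phosphoenolpyruvate in glycolysis, fell. SLK (chromosome 10, 103967201 to 104029233) went from 27.0 ± 4.42 to 46.9 ± 2.38 CPM (log2 fold change 0.79, SE 0.13, edgeR adjusted p = 0.0016). ENO1 (chromosome 1, 8861000 to 8879250) went from 7940 ± 2400 to 3850 ± 1340 CPM (-1.05, SE 0.21, adjusted p = 0.0041). Its 3 controls were at 6410, 10700 and 6710 CPM and its treated libraries at 2830, 5360 and 3350 CPM, so every treated library lay below every control. SF3B1, the protein H3B-8800 binds (chromosome 2, 197389784 to 197435091), rose from 214 ± 17.8 to 310 ± 9.75 CPM (0.53, SE 0.16, adjusted p = 0.021). Removing a trend on GC content and exonic length took SLK to 0.33 (adjusted p = 0.0037) and SF3B1 to 0.06 (adjusted p = 0.58). The SF3B1 call was also lost without DMSO replicate 2 (adjusted p = 0.066), DMSO replicate 3 (0.078) or H3B-8800 replicate 2 (0.064), and the ENO1 call in a fit of these 6 libraries alone (-0.98, adjusted p = 0.11).

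**Figure D2:**
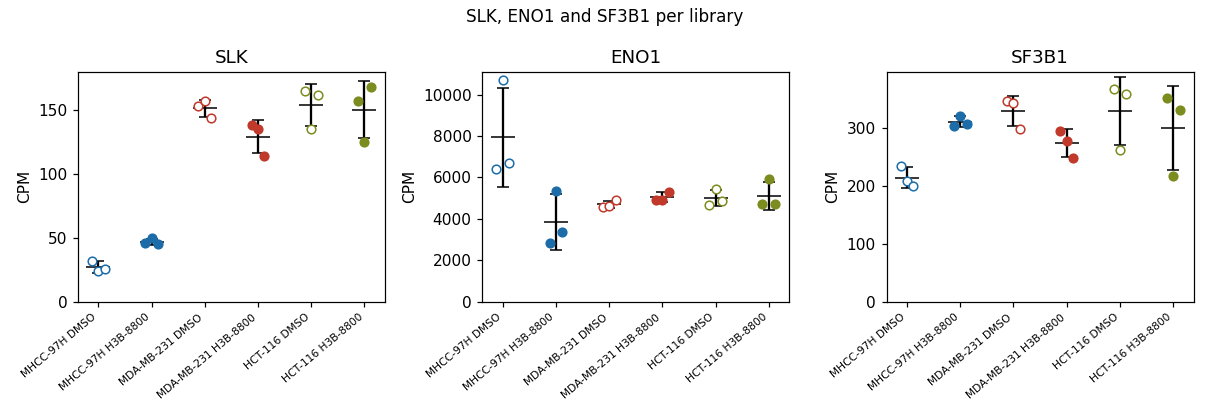
CPM of SLK, ENO1 and SF3B1 (y axes) in every library by group (x axes), with open points for DMSO, filled points for H3B-8800, and bars for mean and SD (n = 3). Under the MHCC-97H label SLK averaged 27.0 CPM with DMSO and 46.9 CPM with H3B-8800, and ENO1 7940 and 3850 CPM.

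Glycolysis genes fell together in the libraries labelled MHCC-97H. Of 25 measured members of the fixed list, 22 fell, 2 rose and 1 was not called. Adjusted over the list alone the counts were also 22 and 2. The neuronal enolase ENO2 fell from 533 ± 17.7 to 179 ± 22.2 CPM (log2 fold change -1.57, SE 0.07, adjusted p = 6.6e-09). The lactate dehydrogenase LDHB (-1.01, SE 0.07, adjusted p = 1.4e-06) and the hexokinases HK2 (-1.45, SE 0.18, adjusted p = 0.00054) and HK1 (-1.02, SE 0.14, adjusted p = 0.00097) fell as well. ENO2 lies on chromosome 12 (6913745 to 6923698), HK2 on chromosome 2 (74833981 to 74893359) and LDHB on chromosome 12 (21635342 to 21757857). The 2 that rose were SLC2A3, a glucose transporter (0.25), and PFKFB2 (0.63), which regulates phosphofructokinase. The list had a median log2 fold change of -0.297 and was called lower by camera (adjusted p = 3.4e-07), though not with an estimated correlation (adjusted p = 0.41 with an estimated correlation). With library totals as the scaling 11 members were called lower, and with the GC and length trend removed 10 were (median -0.109, camera adjusted p = 1.8e-05).

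**Figure D3:**
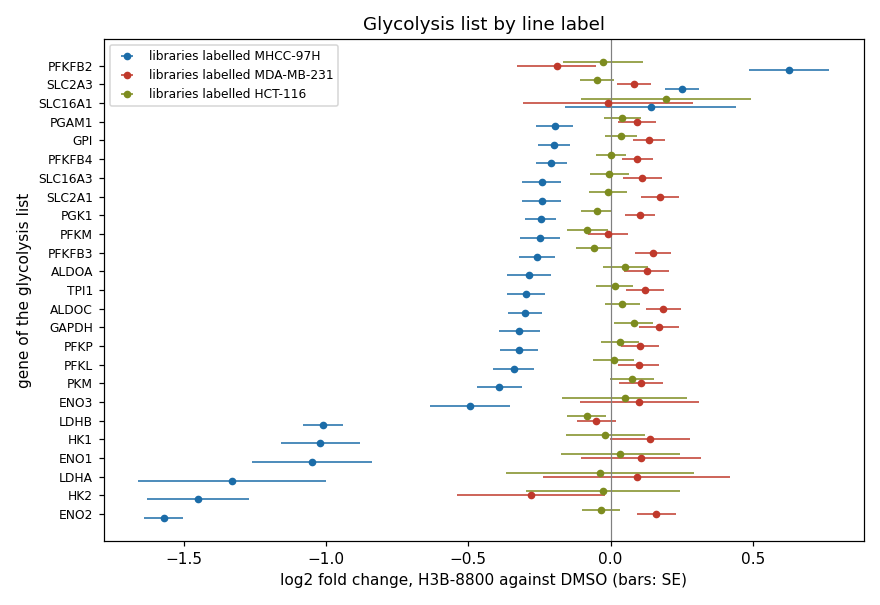
Log2 fold change after H3B-8800 (x axis, bars show the SE) of the 25 genes of the glycolysis list (y axis) under each line label (n = 3 per arm). Under the MHCC-97H label ENO2, HK2, LDHA, ENO1, HK1 and LDHB lie at -1.01 or below, and the other 19 genes between -0.49 and 0.63.

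Of 14234 tested genes, 3922 (27.6%) were called under the MHCC-97H label, 1831 higher and 2091 lower, and 314 changed by at least 1 on the log2 scale, 269 higher and 45 lower. Among called genes averaging at least 10 CPM the largest rises included TET2, an enzyme that oxidises methylated DNA (log2 fold change 1.61, SE 0.30), BIRC6, an inhibitor of apoptosis (1.70, SE 0.42), ZBTB38 (1.92, SE 0.49), DNAJC13 (1.60, SE 0.36), BBX (1.54, SE 0.48) and PHC3 (1.44, SE 0.37). LGALS8, a galectin whose exons overlap HEATR1, rose by 1.59 (SE 0.21). At that level the largest fall was that of TOMM6, a subunit of the mitochondrial import pore, at -2.72 (SE 0.44), while AL365205.1, which overlaps it, rose by 1.91 (SE 0.44). SNX15 (-2.17), AP002990.1 (-1.45), AL133352.1 (-1.26) and BEST1 (-1.22) fell, and each overlaps exons of another gene, so their reads cannot be assigned with certainty. LDHA fell from 1490 ± 36.6 to 593 ± 266 CPM (-1.33, SE 0.33, adjusted p = 0.011). DLD, a subunit shared by several dehydrogenase complexes (1.24, SE 0.06), and ACO1, a cytosolic aconitase (0.97, SE 0.08), rose with adjusted p = 3.7e-08 and 1.5e-05. TET2 lies on chromosome 4 (105145875 to 105279816), TOMM6 on chromosome 6 (41787662 to 41789898) and DLD on chromosome 7 (107890970 to 107931730). With limma voom ZBTB38 (adjusted p = 0.14), BIRC6 (0.059) and DNAJC13 (0.066) were not called, and with the GC and length trend removed BBX (0.25), PHC3 (0.082) and SNX15 (0.05) were not, while TET2 was at 1.05. In a fit of these 6 libraries alone ZBTB38 (0.057), BBX (0.053), PHC3 (0.081), SNX15 (0.06), LDHA (0.066) and BEST1 (0.089) were not called. Leaving out DMSO replicate 1, DMSO replicate 2, H3B-8800 replicate 1 or H3B-8800 replicate 2 also ended the BBX call (adjusted p = 0.072, 0.11, 0.076 and 0.091), and either of the last 2 the SNX15 call (0.056 and 0.059). The replicate block ended the BBX call as well (0.12).

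The balance of rises and falls depended on GC content, gene length and scaling. Across 14223 genes the MHCC-97H log2 fold change had a Spearman rho of -0.53 with GC content and 0.43 with exonic length. Under the labels MDA-MB-231 and HCT-116 the signs were opposite, at 0.31 and 0.18 with GC content and -0.2 and -0.14 with exonic length. Of the 3558 genes lowest in GC content 1014 were called higher and 95 lower, against 16 and 1027 of the 3556 highest. Called genes were 46.7% higher with TMM, 87.8% with library totals (2847 called), 59.9% with upper-quartile factors and 56.0% with the GC and length trend removed (1722 called, of which 1187 were among the 3922 with the same sign). Library totals moved the median of all genes from -0.058 to 0.0392. Without DMSO replicate 2, DMSO replicate 3 or H3B-8800 replicate 2 the count was 2439, 2141 or 2336, and without DMSO replicate 1 the count of changes of at least 1 was 477.

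**Figure D4:**
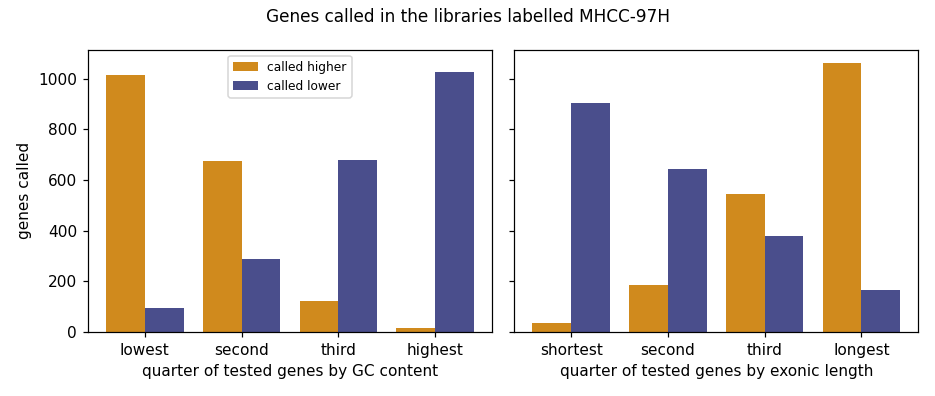
Number of genes called higher and lower after H3B-8800 in the libraries labelled MHCC-97H (y axis), in 4 equal classes of the tested genes by GC content and by exonic length (x axes). In the lowest GC class 1014 genes were called higher and in the highest 1027 lower.

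Under the MHCC-97H label, with TMM scaling, more genes of the ribosome, nuclear-encoded respiration and the proteasome were called lower than higher. More genes of mitosis and DNA repair were called higher than lower. Of 41 cytosolic ribosomal proteins 35 fell and 0 rose (39 lower adjusted over the list alone), such as RPL30 (-0.33, SE 0.05), with camera adjusted p = 3.6e-12 and adjusted p = 0.47 with an estimated correlation. Of 30 nuclear genes of oxidative phosphorylation 16 fell (16 lower and 1 higher adjusted over the list alone), such as ATP5F1C (-0.24) and COX4I1 (-0.28), with adjusted p = 5e-05 and adjusted p = 0.48 with an estimated correlation. Of 30 proteasome genes 15 fell, such as PSMD4 (-0.30), and PSMD1 rose (0.44), with the same counts adjusted over the list alone. The proteasome list had adjusted p = 0.0079 and adjusted p = 0.50 with an estimated correlation. Of 36 genes of mitosis 16 rose and 4 fell (19 and 9 adjusted over the list alone), among them ECT2 (1.08, SE 0.13) and NUSAP1 (0.59, SE 0.09), with adjusted p = 0.0049 and adjusted p = 0.47 with an estimated correlation. Of 30 DNA repair genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), such as the helicase BLM (0.75, SE 0.14) and BARD1 (0.63, SE 0.14), with adjusted p = 0.0022 and adjusted p = 0.47 with an estimated correlation. With library totals 16 ribosomal proteins were called lower, 2 oxidative phosphorylation genes were higher and 3 lower, and 2 proteasome genes higher and 1 lower (list adjusted p = 0.09). With the GC and length trend removed the counts of lower and higher genes were 12 and 1 for ribosomal proteins, 5 and 2 for oxidative phosphorylation (median -0.0746 against -0.26), 3 and 1 for the proteasome and 0 and 4 for DNA repair, and the lists of proteasome (adjusted p = 0.43) and DNA repair (0.099) were no longer called.

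Genes of the splicing machinery were called in both directions under the MHCC-97H label, with a balance that turned with the scaling. Of 20 genes of the SF3b and U2 particle 4 rose, such as the helicase DDX46 (1.04, SE 0.15), and 8 fell, such as SF3B5 (-0.37, SE 0.08) and PHF5A (-0.37, SE 0.09); adjusted over the list alone the counts were 4 and 9, and camera gave adjusted p = 0.32. Of 32 core spliceosome genes 5 rose and 8 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.80, median -0.0544 and mean 0.00952). Of 19 genes of SR proteins and their kinases 6 rose and 2 fell, with the same counts adjusted over the list alone (0.22), and of 23 hnRNP genes 4 rose and 3 fell (5 and 6 adjusted over the list alone, 0.67, median -0.00572 and mean 0.0544). Of 16 genes of nonsense-mediated decay 4 rose, among them SMG1 (1.33, SE 0.32) and UPF2 (1.24, SE 0.31), and 2 fell (also 4 and 2 adjusted over the list alone, 0.73, median -0.0368 and mean 0.165). Of 12 genes reported to respond to splicing inhibitors 1 rose and 3 fell, as adjusted over the list alone (0.56). Of 19 genes with a minor intron 8 rose, such as the exportins XPO7 (0.47, SE 0.08) and XPO4 (1.14, SE 0.21), and 0 fell (8 and 1 adjusted over the list alone), with adjusted p = 0.039 and adjusted p = 0.47 with an estimated correlation. Fry does not compare a list with other genes and called 21 of the 43 lists under this label, so its calls do not single out splicing genes. Fry called the SF3b and U2 list (adjusted p = 0.022), the genes reported to respond to splicing inhibitors (0.0079) and the minor-intron list (0.0025). It did not call the lists of the core spliceosome, SR proteins, hnRNPs and nonsense-mediated decay. With library totals the counts of higher and lower genes were 5 and 1 for the SF3b and U2 particle, 11 and 1 for the core spliceosome, 7 and 0 for SR proteins, 9 and 0 for hnRNPs, 5 and 0 for nonsense-mediated decay and 2 and 0 for the genes reported to respond to splicing inhibitors. With the GC and length trend removed they were 4 and 1, 3 and 0, 2 and 2, 3 and 8, 3 and 0, and 0 and 0. The minor-intron list was not called with the GC and length trend removed (adjusted p = 0.32), nor without DMSO replicate 2 (0.07), DMSO replicate 3 (0.066) or H3B-8800 replicate 2 (0.069). Leaving out 5 libraries of the MDA-MB-231 label, one at a time, also ended it (0.055, 0.06, 0.059, 0.051 and 0.05 without DMSO replicates 1 and 2 and H3B-8800 replicates 1, 2 and 3).

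Genes were also counted by number of introns, with no test between the classes. Of 3057 coding genes with 16 or more introns 30.1% were called higher and 9.62% lower under the MHCC-97H label (median 0.123), against 3.30% and 11.1% of 333 single-exon genes (median -0.126). The comparison of single-exon with other coding genes was not called under the labels MHCC-97H (adjusted p = 0.22), MDA-MB-231 (0.22) or HCT-116 (0.38), nor with an estimated correlation (0.29, 0.29 and 0.42). Restricted to genes averaging at least 10 CPM it was called under each label, lower for MHCC-97H (adjusted p = 0.016, median difference -0.057) and higher for MDA-MB-231 (0.0014, 0.052) and HCT-116 (0.041, 0). These calls were lost with an estimated correlation, chosen for this class after seeing the data (adjusted p = 0.32, 0.31 and 0.32 with an estimated correlation). Across genes the rho of the MHCC-97H log2 fold change with intron number was 0.22, below its size with GC content and exonic length.

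In the libraries labelled MDA-MB-231, 5 genes were called after H3B-8800. RNF138, a ubiquitin ligase, rose from 11.5 ± 0.584 to 28.5 ± 0.659 CPM (log2 fold change 1.30, SE 0.09, adjusted p = 5e-06), and MYADM rose from 210 ± 11.1 to 354 ± 16.1 CPM (0.75, SE 0.06, adjusted p = 1.1e-05). PEX5, the receptor for import into peroxisomes, rose from 62.1 ± 4.19 to 97.1 ± 8.64 CPM (0.64, SE 0.07, adjusted p = 0.00044). TTYH2 fell from 184 ± 4.95 to 82.9 ± 7.20 CPM (-1.15, SE 0.14, adjusted p = 0.0018). RNF138 lies on chromosome 18 (32091855 to 32131561), MYADM on 19 (53866223 to 53876437), PEX5 on 12 (7188685 to 7218574) and TTYH2 on 17 (74213514 to 74262020). SCARA5, named after its values were seen since it lies under 1 CPM, fell by 1.45 (SE 0.23, adjusted p = 0.033). SLK (-0.23, SE 0.12, adjusted p = 0.73), ENO1 (0.11, SE 0.21, adjusted p = 0.95) and SF3B1 (-0.27, SE 0.15, adjusted p = 0.76) were not called. Counts were 6 with limma voom, 57 with DESeq2, 14 in a fit of these 6 libraries alone, 11 with the GC and length trend removed, and 8 without HCT-116 DMSO replicate 3 or without HCT-116 H3B-8800 replicate 2. With the replicate block the calls of TTYH2 (adjusted p = 0.066) and SCARA5 (0.12) were lost. SCARA5 was also lost with limma voom (0.24), in the fit of 6 libraries (0.32) and without any one of 11 libraries (0.053 to 0.39). These were each MHCC-97H library, MDA-MB-231 DMSO replicates 1 and 2, MDA-MB-231 H3B-8800 replicates 2 and 3 and HCT-116 H3B-8800 replicate 1. At an unadjusted p under 0.05 edgeR had 1024.

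Several lists moved slightly under the MDA-MB-231 label, although 0 of their members were called (edgeR, 1024 genes of all at an unadjusted p under 0.05). All 13 measured mitochondrially encoded genes had positive log2 fold changes (median 0.185, 8 higher adjusted over the list alone), with camera adjusted p = 2.1e-08 and adjusted p = 0.47 with an estimated correlation. Glycolysis had a median of 0.103 (adjusted p = 0.00036, adjusted p = 0.48 with an estimated correlation) and the ATF4 stress list 0.0837 (adjusted p = 0.0016, adjusted p = 0.41 with an estimated correlation). Ribosomal proteins had a median of 0.0476 (adjusted p = 0.008, adjusted p = 0.76 with an estimated correlation). The BCL2 family (0.0715, adjusted p = 0.024, adjusted p = 0.41 with an estimated correlation), death receptors and inhibitors of apoptosis (0.0893, adjusted p = 0.036, adjusted p = 0.41 with an estimated correlation) and autophagy genes (0.0812, adjusted p = 0.027, adjusted p = 0.47 with an estimated correlation) were also called higher. DNA repair (-0.151, adjusted p = 0.0094, adjusted p = 0.50 with an estimated correlation) and colon markers (-0.0793, adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation) were called lower. By fry the lists of glycolysis (adjusted p = 0.13), mitochondrially encoded genes (0.099), the BCL2 family (0.13), DNA repair (0.19), ribosomal proteins (0.54) and autophagy (0.063) were not called. Adjusted over the list alone 1 gene was higher in the ATF4 list and 1 in the autophagy list, 1 was lower among colon markers, and 0 were called in glycolysis, ribosomal proteins, the BCL2 family, death receptors and DNA repair. Without DMSO replicate 2 of this label 5 lists were called in place of 9 (BCL2 0.069, death receptors 0.077, DNA repair 0.091 and ribosomal proteins 0.14 were lost). Without H3B-8800 replicate 3 of this label the lists of the BCL2 family (0.058), ribosomal proteins (0.05), autophagy (0.05) and colon markers (0.11) were lost. Death receptors were also lost without DMSO replicates 1 and 3 and H3B-8800 replicate 2 (0.059, 0.054 and 0.089), the BCL2 family without DMSO replicate 1 (0.069), and autophagy without DMSO replicate 3 and H3B-8800 replicate 1 (0.079 and 0.068). With library totals the ribosomal call ended (0.078), with the block that of death receptors (0.11), and with the GC and length trend removed the ribosomal (0.49), BCL2 (0.066) and DNA repair (0.098) calls ended.

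In the libraries labelled HCT-116, 5 genes were called. PNKD rose from 60.6 ± 1.95 to 123 ± 6.15 CPM (log2 fold change 1.02, SE 0.06, adjusted p = 5.6e-07). ASNS, asparagine synthetase, rose from 97.4 ± 6.23 to 135 ± 4.77 CPM (0.47, SE 0.06, adjusted p = 0.0025), and PSAT1, an enzyme of serine synthesis, from 93.9 ± 2.82 to 127 ± 3.05 CPM (0.43, SE 0.04, adjusted p = 0.00031). PEX5 rose (0.47, SE 0.07, adjusted p = 0.016), and SEC24C, a coat protein of transport vesicles, fell from 160 ± 1.71 to 111 ± 5.13 CPM (-0.53, SE 0.08, adjusted p = 0.027). PNKD lies on chromosome 2 (218270392 to 218346793), ASNS on 7 (97852118 to 97872542), PSAT1 on 9 (78297143 to 78330093) and SEC24C on 10 (73744384 to 73772161). SLK (-0.04, SE 0.12, adjusted p = 1), ENO1 (0.03, SE 0.21, adjusted p = 1) and SF3B1 (-0.13, SE 0.15, adjusted p = 1) were not called. Counts were 6 with limma voom, 24 with DESeq2, 1 in a fit of these 6 libraries alone (where ASNS had adjusted p = 0.6, PSAT1 0.42, PEX5 0.35 and SEC24C 0.26), 3 without DMSO replicate 2 or DMSO replicate 3, and 15 without H3B-8800 replicate 1; at an unadjusted p under 0.05 edgeR had 655. With the replicate block the SEC24C call was lost (adjusted p = 0.058), as it was with RLE size factors (0.052), with upper-quartile factors (0.065) and without any one of the 6 MHCC-97H libraries, MDA-MB-231 DMSO replicates 1 and 2, or 5 of the HCT-116 libraries other than H3B-8800 replicate 2 (0.052 to 0.13). The PEX5 call was lost without any one of HCT-116 DMSO replicates 1, 2 and 3 and H3B-8800 replicates 2 and 3 (0.052 to 0.12).

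Under the HCT-116 label 2 lists were called higher. Of 24 genes of the ATF4 stress response ASNS and PSAT1 rose, 7 were higher adjusted over the list alone, and the median was 0.155 (camera adjusted p = 7.7e-10, adjusted p = 0.14 with an estimated correlation). All 13 mitochondrially encoded genes had positive log2 fold changes, 0 were called by edgeR over all genes (655 at an unadjusted p under 0.05), and 11 were higher adjusted over the list alone (median 0.243, adjusted p = 4.7e-16, adjusted p = 0.41 with an estimated correlation). Called lists numbered 4 with the replicate block, 4 with the GC and length trend removed, 5, 4, 4, 6 and 7 without DMSO replicates 2 and 3 and H3B-8800 replicates 1, 2 and 3 of this label, and 0 with an estimated correlation.

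PSAT1, PNKD, MYADM, RNF138 and SEC24C, called after treatment under 1 of these 2 labels, were also the 5 genes called between their DMSO groups. RNF138 was at 11.5 CPM in the MDA-MB-231 DMSO group and at 28.5, 28.5 and 28.1 CPM in the other 3 groups of the 12 libraries. PNKD was at 60.6 CPM in the HCT-116 DMSO group and at 118, 119 and 123 CPM in the others. With the 12 libraries fitted together, PEX5 was the one gene called by treatment (log2 fold change 0.56, adjusted p = 0.0041), with 901 at an unadjusted p under 0.05.

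The H3B-8800 effect differed between line labels for 2197 genes (15.4%) in the interaction test. ENO2 had the smallest adjusted p (2.6e-07), with a difference of -1.74 between the MHCC-97H and MDA-MB-231 labels and -1.54 between MHCC-97H and HCT-116. DLD (1.40 and 1.21), LDHB (-0.96 and -0.92) and ACO1 (1.04 and 1.05) followed the same division. PNKD, RNF138, MYADM and TTYH2 completed the 8 smallest. For SLK the difference was 1.02 (SE 0.17, adjusted p = 0.0047) from MDA-MB-231 and 0.83 (SE 0.17, adjusted p = 0.016) from HCT-116. For ENO1 it was -1.15 (SE 0.29, adjusted p = 0.017) and -1.08 (SE 0.29, adjusted p = 0.032). The glycolysis list differed by a median of -0.418 from MDA-MB-231 (adjusted p = 3.6e-08, adjusted p = 0.52 with an estimated correlation) and -0.338 from HCT-116 (adjusted p = 2.5e-06, adjusted p = 0.52 with an estimated correlation). Between the MDA-MB-231 and HCT-116 labels 5 genes differed by edgeR (588 at an unadjusted p under 0.05). Camera at the preset correlation also called lists between these labels. Among them were glycolysis (median 0.0908, adjusted p = 0.007, 0.52 with an estimated correlation), hypoxia (adjusted p = 0.017), autophagy (0.028) and ribosomal proteins (0.034). Such calls thus also arose between labels that share one profile. Pairwise, 2871 genes differed between MHCC-97H and MDA-MB-231, and 1878 between MHCC-97H and HCT-116.

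Genes with the largest pairwise differences lay near the detection floor under one label. RNF144A had 0 counts in the MHCC-97H controls and 0.151 ± 0.0719 CPM after treatment, against 24.3 ± 0.96 and 24.2 ± 1.66 CPM under the MDA-MB-231 label. QPCT was at 0.165 ± 0.166 CPM in the MHCC-97H controls and 0 counts after treatment, against 163 ± 4.64 and 158 ± 1.61 CPM. The readthrough models SENP3-EIF4A1 and MICOS10-NBL1 share exons with their component genes and were not called (adjusted p of the interaction 0.30 and 0.088).

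The count of 2197 rose to 3585 with the replicate block and fell to 873 with the GC and length trend removed. It was 670 and 565 without MHCC-97H DMSO replicates 2 and 3, 899, 781 and 1416 without MHCC-97H H3B-8800 replicates 1, 2 and 3, 1282 and 1306 without MDA-MB-231 DMSO replicates 1 and 2, 1326 without MDA-MB-231 H3B-8800 replicate 3, and 1441 without HCT-116 DMSO replicate 3. The count for MHCC-97H against MDA-MB-231 was 1675, 1793, 1470, 1832, 1602 and 1806 without MDA-MB-231 DMSO replicates 1 and 2, MDA-MB-231 H3B-8800 replicate 3, MHCC-97H DMSO replicates 2 and 3 and MHCC-97H H3B-8800 replicate 2. For MHCC-97H against HCT-116 the block gave 3320, and leaving out HCT-116 DMSO replicates 1, 2 and 3, HCT-116 H3B-8800 replicate 2, MHCC-97H DMSO replicates 2 and 3 and MHCC-97H H3B-8800 replicates 1 and 2 gave 345, 2841, 322, 847, 545, 460, 797 and 644. Between MDA-MB-231 and HCT-116 it was 25 with DESeq2 and 9 without HCT-116 DMSO replicate 3.

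No gene was called with one sign under all 3 labels (0 by edgeR, 5 at an unadjusted p under 0.05, where independent lists would give 4.54; 0 also with every other fit tried). Among genes moving one way, VPS26A, a part of the retromer, rose under MHCC-97H (0.92, adjusted p = 0.023) and had 0.32 and 0.44 under the other labels. NUDT16L1 fell under MHCC-97H (-0.80, adjusted p = 0.037) and had -0.39 and -0.69. RNF4, RNMT, JRK, API5, RABGEF1, TMEM132A and NIBAN1 had 3 positive values, and KIRREL1, FAM47E-STBD1, NUDT4, SLPI, KRT17, ISY1-RAB43 and TNIP2 3 negative ones, with adjusted p of 0.11 or more under each label. Across 14234 genes the log2 fold changes of MHCC-97H and MDA-MB-231 had r -0.084 and rho -0.30, those of MHCC-97H and HCT-116 -0.029 and -0.166, and those of MDA-MB-231 and HCT-116 -0.013 and 0.138. Without HCT-116 H3B-8800 replicate 2 the last 2 rho turned to 0.206 and -0.107, and without HCT-116 DMSO replicate 1 they were -0.002 and 0.016. The rho of MHCC-97H and HCT-116 was -0.306, -0.048 and -0.289 without HCT-116 DMSO replicate 2, DMSO replicate 3 and H3B-8800 replicate 3, and that of MDA-MB-231 and HCT-116 was 0.224, 0.054 and 0.213 without HCT-116 DMSO replicate 2, DMSO replicate 3 and H3B-8800 replicate 1. Without MDA-MB-231 H3B-8800 replicate 3 the rho of MHCC-97H and MDA-MB-231 was -0.187.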

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

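The tests of one line under both labels, of libraries deposited under 2 labels, of reads shared between paralogs and of the 6 enzymes with the trend removed were chosen only after the result was seen, as was the fit of 12 libraries.

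The H3B-8800 effect differed between the 3 line labels for 2197 genes in the interaction test. The SLK effect under the MHCC-97H label exceeded that under the MDA-MB-231 label by 1.02 on the log2 scale (adjusted p = 0.0047). The ENO1 effect differed between these labels by -1.15 (adjusted p = 0.017), and the glycolysis list by a median of -0.418 (adjusted p = 3.6e-08, adjusted p = 0.52 with an estimated correlation). Camera at the preset correlation also called glycolysis between the MDA-MB-231 and HCT-116 labels (median 0.0908, adjusted p = 0.007). Of 100 splits of the libraries within labels, 2 gave as many genes as the real 2197, the real one included, but the 90 that regroup the MHCC-97H libraries remove the treatment effect there and gave at most 6. The 9 other splits that kept the MHCC-97H libraries as labelled gave 50, 52, 64, 69, 89, 615, 784, 875 and 3121 genes, the last being the highest other. Among the 10 splits that keep that label 2 thus gave as many as the real one, so whether the count of the interaction exceeds what chance gives in the other 12 libraries stays open. All splits were drawn without regard to the HCT-116 pairs and fitted without the replicate block. The block raised the real count, and no other split was fitted with it.

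The libraries labelled MDA-MB-231 and HCT-116 share one profile, and cells of one line under both labels are a candidate explanation: 5 genes were called between their DMSO groups, against 11772 between those of MHCC-97H and MDA-MB-231. Over the 12 libraries 0 genes were called by line label (edgeR, 524 at an unadjusted p under 0.05). The count of other splits decides nothing here, since any split gives at least 0 (100 of 100, with 2 genes in the highest other). Deposit of the same libraries under both labels is excluded, since the most alike pair across the labels differed by 4.73 times the counting error (median chi-square ratio). No biological explanation was tested for this likeness, and which line the cells are stays open.

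For the 3922 genes called under the MHCC-97H label, library size is excluded as the cause, since 97.93% of the number of calls was left after thinning the 6 libraries to 1 total. A bias in GC content and gene length stays open: with that trend removed 43.91% of the number of calls was left, and a treatment effect on long genes low in GC cannot be told apart from a bias that differs between the arms. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split gave 3922 genes and the highest other 3 (1 of 10 as many, the real one). Under the MDA-MB-231 and HCT-116 labels the 10 splits are also too few, with 5 genes in the real split and 2 in the highest other under each, as also among the 4 HCT-116 splits that part all 3 numbered pairs.

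For the fall of glycolysis genes under the MHCC-97H label, reads moving from one of these paralogs to another are not the whole cause. The sums over ENO1 to ENO3, HK1 and HK2, and LDHA and LDHB also fell, the least by 1.06 on the log2 scale (-1.06). ENO1, ENO2 and both members of the other families had each fallen, so the sums add little to those values. They cannot show whether reads of one paralog carried the fall of another, nor reads lost to genes that were not counted. The trend on GC content and length is excluded as the whole cause for ENO1, ENO2, HK1, HK2, LDHA and LDHB, whose median was -1.161 with the trend removed, all 6 called. For the whole list it stays open, since 10 of 25 members were called lower with the trend removed against 22 without. These 6 enzymes stand apart from the other 19 members (-0.49 to 0.63) and made up 6 of the 12 called genes averaging at least 10 CPM that fell by 1 or more, while 125 rose by as much (6 of 7 and 23 at 50 CPM, a level chosen after the values were seen). The glycolysis list and ENO1 were fixed before the data were seen, while the set of 6 was picked for falls of at least 1. H3B-8800 is the difference between the arms that the labels give, but other differences between the arms were not tested. An effect of H3B-8800 on the 6 is thus a candidate only. In a fit of the 6 libraries of this label alone ENO1 and LDHA were not called. Why the 6 enzymes stand apart was not tested.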

How the results depend on the processing

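The removal of the GC and length trend, the fit of 12 libraries and the thinning were chosen after seeing the data. Of 1364 values under the alternatives, 1224 kept their side of the threshold, 140 lost the call and 0 changed direction with a call in either fit. Direction was not compared for values called in neither fit. The values were those of the called genes with the largest rise or fall, the called lists, and SF3B1. The cause was not tested for the changes below. Library totals left 0 changes of at least 1 under HCT-116. The replicate block gave 3585 genes for the interaction, 3320 for MHCC-97H minus HCT-116 and 4 lists under HCT-116. With the GC and length trend removed the counts were 1722 under MHCC-97H (89 of at least 1), 11 under MDA-MB-231, 0 of at least 1 under HCT-116, 873 for the interaction, 1144 and 641 for MHCC-97H minus MDA-MB-231 and minus HCT-116, and 4 lists under HCT-116; r and rho of MHCC-97H and MDA-MB-231 were -0.04 and -0.157. With the block as well these counts were 1977, 97, 13, 0, 1238, 1541, 1158 and 4. Camera with an estimated correlation called 0 lists under every label (18 with the preset one, and fry 30, of which 21 under MHCC-97H; fry kept 3 of the 9 under MDA-MB-231). Over genes averaging at least 10 CPM, r and rho were -0.288 and -0.443 for MHCC-97H and MDA-MB-231 and 0.17 and 0.22 for MDA-MB-231 and HCT-116, and r was -0.093 for MHCC-97H and HCT-116. There the single-exon genes differed by -0.057 under MHCC-97H, 0.052 under MDA-MB-231 and 0 under HCT-116, all called, and none with an estimated correlation. Against a log2 fold change of 1, glmTreat called 2, 0 and 0 genes, and neither SLK (0.7942) nor ENO1 (-1.045) under MHCC-97H. DESeq2 called 57 genes under MDA-MB-231 (20 of at least 1), 24 under HCT-116 (11 of at least 1) and 25 for their difference. Fits of 6 libraries gave ENO1 -0.9847 (not called), 14 genes under MDA-MB-231 (10 of at least 1) and 1 under HCT-116. The fit of 12 libraries gave 1.

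Leaving out each library in turn gave 2141 to 4455 genes under MHCC-97H (212 to 477 of at least 1), 4 to 8 under MDA-MB-231 (2 to 5) and 3 to 15 under HCT-116 (1 to 4). The interaction had 565 to 2784 genes, and the pairwise differences 1470 to 3661 (MHCC-97H minus MDA-MB-231), 322 to 2841 (MHCC-97H minus HCT-116) and 5 to 9 (MDA-MB-231 minus HCT-116). For these 3 pairs r ran from -0.104 to -0.041, -0.075 to 0.022 and -0.054 to 0.025, and rho from -0.333 to -0.187, -0.306 to 0.206 and -0.107 to 0.224. Called lists numbered 13 to 26, with 6 to 9, 5 to 11 and 2 to 7 under the 3 labels. Each removal also let more genes pass the filter, at 14389 to 14413 against 14234. A lost call near 0.05 therefore need not rest on the library removed. Without MHCC-97H DMSO replicate 1, for example, SEC24C stayed at -0.53 under HCT-116 and SCARA5 at -1.45 under MDA-MB-231. Depth limits genes near the floor of 0.0142 CPM.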

Other observations

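The tests of the mitochondrially encoded share and the removal of the GC and length trend were chosen after the result was seen; the gene lists were fixed in advance.

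Further metabolic lists were measured under the MHCC-97H label. No list in this or the next paragraph was called by camera there, and the balance of several turned with library totals as the scaling. Fry, run with TMM scaling only, called the lists of hypoxia (adjusted p = 0.0011), STE20 kinases (0.0025) and cholesterol (0.03). It also called those of phosphoenolpyruvate (0.018) and pentose phosphate (0.018), but not those of the citrate cycle and YAP targets. Of 21 genes of the citrate cycle 7 fell, such as SUCLG1 (-0.28) and IDH2 (-0.28), while DLD rose (2 higher and 9 lower adjusted over the list alone, adjusted p = 0.45). Of 7 genes making phosphoenolpyruvate and glucose 5 fell, such as PCK2 (-0.34) and MDH2 (-0.22), with 5 also adjusted over the list alone (0.19), and of 7 pentose phosphate genes 4 fell, such as TALDO1 (-0.36) and TKT (-0.33), with 5 adjusted over the list alone (0.069). Of 24 cholesterol synthesis genes 3 rose and 7 fell (4 and 9 adjusted over the list alone, 0.32), among them FDPS (-0.27) and MVD (-0.42). Of 18 hypoxia genes KDM3A rose (0.50) and 5 fell, such as NDRG1 (-0.22), with 1 and 7 adjusted over the list alone (0.54). Of 24 kinases of the STE20 group 8 rose, among them SLK, PAK2 (0.34) and TAOK1 (1.22, SE 0.23), and 2 fell, with 8 and 2 adjusted over the list alone (0.12). Of 14 YAP targets PTPN14 (0.75) and CRIM1 (0.28) rose, as adjusted over the list alone (0.63). With library totals the counts of higher and lower genes were 3 and 1 for the citrate cycle, 0 and 1 for the phosphoenolpyruvate and for the pentose phosphate genes, 4 and 3 for cholesterol, 3 and 0 for hypoxia and 9 and 0 for STE20 kinases. With the GC and length trend removed they were 1 and 0, 0 and 0, 0 and 0, 2 and 1, 2 and 6, and 3 and 1.

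Stress and signalling lists under the MHCC-97H label were counted in the same way. Fry called the intronless, autophagy and p53 lists (adjusted p = 0.0011 each) and that of immediate early genes (0.0064). It also called the lists of NF-kB (0.015), the BCL2 family (0.019) and NRF2 (0.046), and no other list of this paragraph. Of 34 intronless genes 1 rose and 10 fell (2 and 11 adjusted over the list alone, adjusted p = 0.056), among them HSPA1A (-0.45, SE 0.05) and IER5 (-0.37). Of 26 immediate early genes 1 rose and 8 fell, also over the list alone (0.062), such as DUSP4 (-0.21). Of 20 autophagy and lysosome genes 6 fell (8 adjusted over the list alone, 0.056), such as CTSB (-0.27). Of 25 p53 targets 1 rose and 8 fell (2 and 9 adjusted over the list alone, 0.34), such as GDF15 (-0.40), and of 24 ATF4 genes 4 rose, such as GARS1 (0.31), and 7 fell, such as ATF4 (-0.22), with 5 and 8 adjusted over the list alone (0.52). Counts of called higher and lower genes were 4 and 4 of 18 for the unfolded protein response (the same over the list alone, 0.80), 2 and 5 of 15 for heat shock (3 and 5, 0.63), 1 and 5 of 21 for NF-kB (the same, 0.32) and 4 and 2 of 26 for interferon (the same, 0.78). They were 0 and 4 of 15 for the BCL2 family (the same, 0.29), 2 and 3 of 23 for death receptors and inhibitors (the same, 0.80), 2 and 7 of 16 for NRF2 (4 and 7, 0.61) and 3 and 8 of 36 for S phase (the same, 0.44). Ribosome biogenesis had 3 and 7 of 27 (4 and 7, 0.65), EMT 2 and 3 of 19 (the same, 0.86), replication histones 0 and 3 of 24 (0 and 2, 0.41) and snoRNA hosts 1 and 0 of 2 (the same, 0.73). The median and mean of a list differed in sign for the unfolded protein response, death receptors, ribosome biogenesis, NRF2 and EMT, and the test of interferon genes pointed up while both were below 0. With library totals the counts of higher and lower genes were 3 and 3 for intronless genes, 1 and 1 for immediate early and for autophagy genes, 3 and 2 for p53, 4 and 0 for ATF4, 6 and 0 for the unfolded protein response, 4 and 2 for heat shock, 2 and 0 for NF-kB and 6 and 0 for interferon. They were 1 and 1 for the BCL2 family, 6 and 0 for death receptors, 4 and 0 for NRF2, 5 and 0 for S phase, 8 and 0 for ribosome biogenesis, 2 and 2 for EMT and 0 and 0 for histones. With the GC and length trend removed the same lists in that order had 2 and 5, 2 and 3, 0 and 4, 0 and 1, 2 and 1, 3 and 2, 2 and 2, 0 and 1, 1 and 0, 0 and 1, 1 and 3, 1 and 2, 2 and 0, 2 and 1, 1 and 1, and 0 and 0. Markers of other cells had 0 and 1 of 16 for liver (FGB), 0 and 0 of 11 for colon, 0 and 2 of 12 for basal breast (PLAU, LOXL2; 2 and 0 with library totals), 1 and 0 of 5 for blood (LYZ) and 0 and 0 of 8 for stroma; edgeR had 5575 genes of all at an unadjusted p under 0.05.

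The share of counts from the 13 mitochondrially encoded genes was higher after H3B-8800 under each label, at 1.17% ± 0.04 and 1.38% ± 0.012 under MHCC-97H, 6.38% ± 0.038 and 7.03% ± 0.31 under MDA-MB-231, and 6.21% ± 0.44 and 7.24% ± 0.68 under HCT-116 (DMSO and H3B-8800, SD, n = 3). An exact permutation test within labels, on the difference summed over labels (1.88 percentage points), gave a one-sided p = 0.001375, from 8000 arrangements. The direction of this test and of its paired form was set after the shares were seen. Labels with a larger share weigh more in the sum, so it does not test each label. With the HCT-116 libraries paired by number, all 3 pairs were higher after H3B-8800, and the exact test gave a one-sided p = 0.000312, the smallest that its 3200 arrangements allow. Paired, the HCT-116 exact test gave a two-sided p = 0.25, the lowest that 3 pairs allow. Unpaired, the exact permutation test per label gave a two-sided p = 0.1, 0.1 and 0.2, and 0.1 is the lowest that 3 against 3 allows. Under the MHCC-97H label 3 of the 13 genes were called higher, such as MT-ND5 (0.25), with camera adjusted p = 0.12. With an estimated correlation camera gave adjusted p = 0.76, and fry gave adjusted p = 0.39. With library totals 7 were higher, and with the GC and length trend removed 11 were, with camera adjusted p = 6.1e-08. An estimated correlation was not tried with the trend removed.

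In the 12 libraries labelled MDA-MB-231 or HCT-116 the first principal component held 15.9% of the variance. Across genes its loading had a rho of 0.56 with GC content and -0.52 with the MHCC-97H log2 fold change. HCT-116 H3B-8800 replicate 2 lay at 43.8 on it, and the next library at 20. The component did not part the treatments under the HCT-116 label. DMSO replicate 2 lay at 17.7 there, and H3B-8800 replicates 1 and 3 at -17 and -14.1. Under these labels the lists not described in the report were not called by camera.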
